A study of Mus musculus with 24 samples.

How the data were processed

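Naive CD4 T cells of 129SvEv mice, wild-type or double knockout for Batf and Batf3, were profiled on 24 Affymetrix mouse gene arrays with probe sets spread along whole transcripts. Per the labels, cells were activated with soluble anti-CD3e and with anti-CD28 held by plate-bound antibody under TH2-polarising culture, and biotin-labelled target was hybridised. The 8 groups are the 4 states (day 0, day 2, day 4 with 2.2 ng/ml and day 4 with 10 ng/ml of anti-CD3e) in each genotype, with 3 arrays each, mapped from the sample labels.

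The deposited values are intensities made by the authors with RMA (background correction, quantile normalization and probe summary), per the submitters' processing notes. The software and its version are not given in the sources used here. The table holds 35556 probe sets, and its values run from 1.95 to 14644.9 on a linear scale, so log2 was taken before any test. Quantile normalization forces nearly the same distribution on every array, so a change shared by most genes is removed, and background intensity compresses folds of dim genes. The median of the probe set means, an intensity of 28.6, was used as a guide: a level at or below it may be background, and a fold against such a level understates the change. No scan date or batch is given in the sources used here, so none was tested. For arrays only their number limits the precision.

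Probe sets were named from the platform annotation: 21789 carried 1 gene symbol, 1621 several and 12146 no listed gene, and the last 2 kinds were left out of the gene tests. Of the named probe sets, 21698 matched the RefSeq mouse gene table (GRCm38.p6) by Entrez number, and this changed 0 symbols. No build is named for the arrays, so no coordinates are given. For the 999 genes with several probe sets, the one with the highest mean was used, which left 19938 genes. Probe sets of one gene were called in both directions for at most 13 genes in any contrast. Paralogs with similar sequence, such as Mt1 and Mt2, Lilrb4a and Lilr4b, and the Ms4a and Ifi200 families, may share signal.

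Tests used limma 3.58.1 in R 4.3.3. One model with a mean for each of the 8 groups was fitted to all 24 arrays, with 16 residual degrees of freedom and empirical Bayes moderation (7.49 prior degrees of freedom), and 11 contrasts were read from it: 3 for activation, 4 for genotype within a state, 2 for dose within a genotype, and 2 interactions. P-values were adjusted by Benjamini-Hochberg within each contrast, and an adjusted p under 0.05 was called. A fold change is the ratio of geometric means, with a 95% confidence interval from the moderated standard error.

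Gene lists were fixed before the data were examined: 27 lists with 373 genes, of which 335 were measured, covering T cell subsets, receptors, transcription factors, metabolism, division, stress and markers of other cell types. The rest were not analysed here. Each list was tested with camera at its preset correlation between genes of 0.01, and again with an estimated correlation; adjusted p-values are over the 27 lists of a contrast. Of 108 list shifts called, 66 held with an estimated correlation, and the p from the estimated correlation is given wherever a call was lost.

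Named genes follow a rule fixed before the data were examined. In each contrast these are Batf, Batf3 and Irf4; the 10 largest rises and the 10 largest falls among called genes, which in a contrast of 2 groups also had to show no overlap between the 3 arrays of each group; and from each list up to 4 members with the smallest p. Predicted gene models, small RNA genes, antigen receptor segments, X-inactivation and Y-linked genes and probe sets with several symbols were skipped, and which genes of the rule are printed was chosen with their values in view. The design, groups and most alternatives were also fixed before the data were examined.

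Alternatives were a filter on dim genes, every probe set counted once, the mean of a gene's probe sets, cyclic loess or quantile normalization on top of the deposited values, a fit of the compared groups alone, the replicate number as a block, a variance trend with robust moderation, array weights, and each array left out in turn. Leaving out 2 WT arrays together (2.2 ng/ml replicate 3 and day 2 replicate 3), leaving out single arrays in the list tests and leaving Batf and Batf3 out of their list were added after the data were seen.

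Tests were checked for the day 2 genotype contrast on data simulated from means and residual spread of the 19938 genes. Of 50 genes changed by 0.5 on the log2 scale, 13 were recovered, of 50 changed by 1, 47, and all 50 at 2 and at 3. Among 173 calls, 9 fell on unchanged genes and 4 on the 15 genes of a list shifted by 0.5. Camera called that list, not an unshifted one. Correlated genes were not simulated.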

Results

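Expression was measured in mouse naive CD4 T cells on 24 gene arrays. The cells came from wild-type (WT) 129SvEv mice or from mice carrying a double knockout of Batf and Batf3 (DKO), a pair of basic leucine zipper factors that bind DNA together with Irf4. The series title and labels ask how T cells translate the strength of T cell receptor stimulation into graded transcription through Batf and Irf4. Cells were taken unstimulated at day 0, or after culture under TH2 conditions for 2 days, or for 4 days with 2.2 or 10 ng/ml of anti-CD3e, the antibody that triggers the T cell receptor. The labels give no anti-CD3e concentration for day 2. Each of the 8 groups held 3 arrays, and 19938 genes were tested. Levels are mean array intensities ± SD over 3 arrays. Fold changes come from limma with their 95% confidence interval (CI), and log2 fold changes carry their standard error. The labels do not say whether replicates were separate mice or cultures, so the p-values measure the spread between these samples, which may be technical.

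Activation separated the arrays along the first principal component, which held 52.5% of the variance. WT cells at 10 ng/ml lay apart from every other group on the second, which held 14.9%. Arrays of a group correlated with each other at 0.983 to 0.992, and array medians ran from 26.4 to 31.6. WT replicate 3 at 2.2 ng/ml held Irf4 at 588 against 338 and 267 in the others, and Il4 at 99.9 against 22.2 and 18.1. An alternative left out this array and WT day 2 replicate 3 (the 2 WT arrays). The latter read Ctla4 at 260.1 against 620.4 and 642, but its log2 residual SD of 0.148 was the lowest of 24. WT day 0 replicate 3 had the highest, 0.21.

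**Figure D1:**
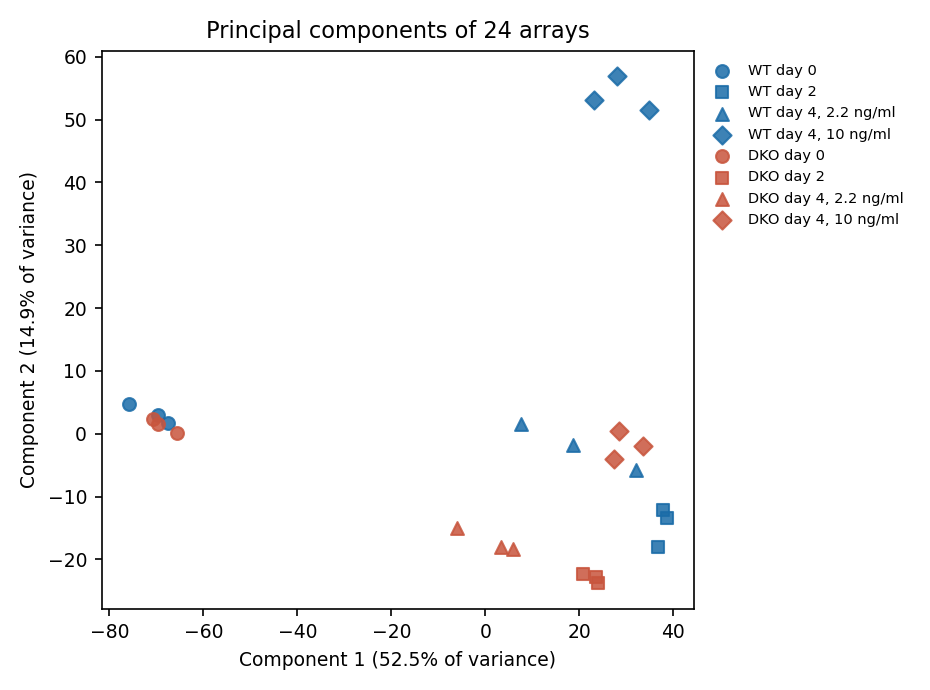
Scores of the 24 arrays on the first principal component (x axis, 52.5% of variance) and the second (y axis, 14.9%), from log2 intensities of all tested genes; colour gives the genotype and marker shape the state. The 6 unstimulated arrays form one cluster at the left, and the 3 WT arrays at 10 ng/ml lie alone at the top.

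The knocked-out genes were read first. Batf stood at 135 ± 20.9 in naive WT cells, 722 ± 137 at day 2, 1509 ± 125 at 2.2 ng/ml and 1595 ± 99.8 at 10 ng/ml. In DKO cells it was 31.2 ± 3.16, 32.5 ± 5.12, 32.2 ± 4.99 and 46.5 ± 4.87 in the same order, so all 12 DKO arrays lay below all 12 WT arrays. Batf3 was near the array background in WT cells except at 10 ng/ml, where it reached 146 ± 32.8 against 29.8 ± 4.57 in DKO cells, the one state in which it could check the label. Irf4, the partner factor, was not knocked out. It rose from 32.8 ± 7.895 in naive WT cells to 1123 ± 25.7 at day 2, and stood at 398 ± 169 at 2.2 ng/ml and 1304 ± 101 at 10 ng/ml. DKO cells held Irf4 at 31.9 ± 5.32, 707 ± 84.8, 350.2 ± 68.7 and 896 ± 68.4.

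**Figure D2:**
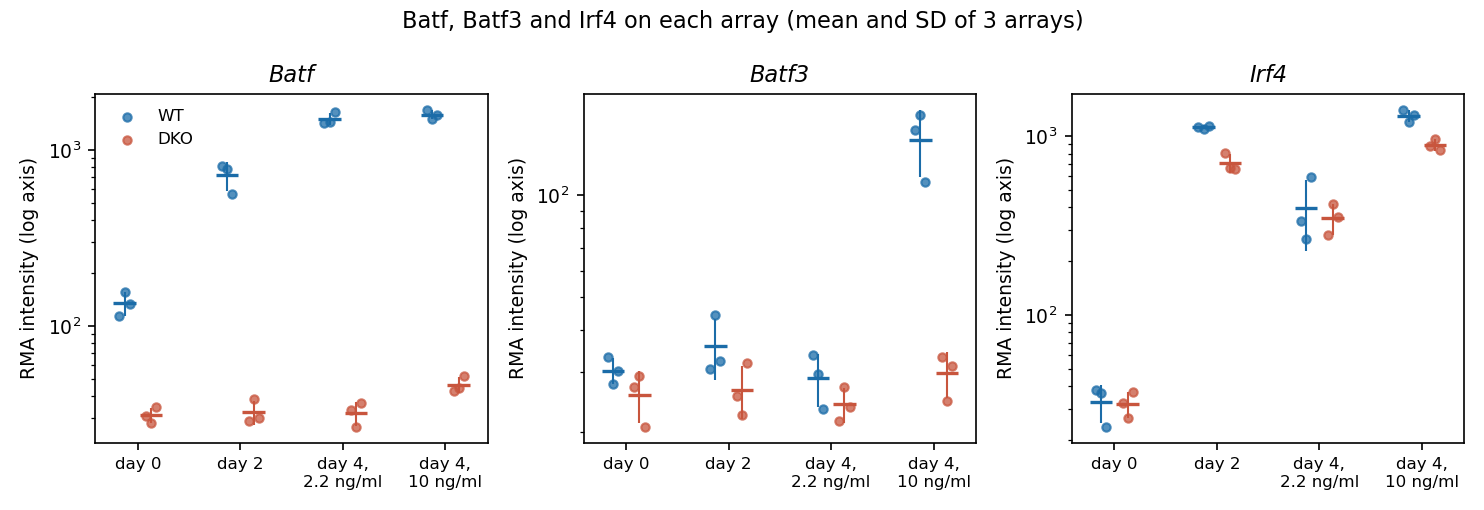
RMA intensity (y axis, log scale) of Batf, Batf3 and Irf4 on each array by state (x axis), in WT (blue) and DKO (red); points are arrays, horizontal lines means and vertical lines SD of 3 arrays. Batf lies at 31.2 to 46.5 in the DKO group means, and Batf3 rises above its other levels in WT at 10 ng/ml.

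After 2 days of TH2 culture, the mitosis, DNA replication, glycolysis and TH2 lists were higher in WT cells and the naive list lower. Il2ra, the alpha chain of the interleukin-2 receptor, rose 162-fold (95% CI 119.8 to 218) from 16.02 ± 7.44 to 2415 ± 162, and the cytokine Lif rose 84.2-fold (95% CI 58.8 to 121). Irf4 rose 35.03-fold (95% CI 25.8 to 47.6) and Batf 5.33-fold (95% CI 4.26 to 6.65), whereas Batf3 did not pass the test (30.4 ± 2.75 and 35.8 ± 7.33, adjusted p = 0.37). Falls included S1pr1, the receptor that lets lymphocytes leave lymph nodes, which fell 22.2-fold (95% CI 15.1 to 32.7), the interferon-inducible gene Samd9l (51.4-fold), the naive T cell membrane protein Ms4a4b (42.4-fold) and Il18r1, an interleukin-18 receptor chain (30.3-fold).

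All 15 measured genes of the mitosis list rose, among them Top2a (51.7-fold, 10.3-fold as the mean of its probe sets) and Mki67 (46.9-fold), as did all 17 of the DNA replication list. Rrm2, a subunit of ribonucleotide reductase, rose 32.9-fold and the helicase subunit Mcm6 13.6-fold. All 12 glycolysis genes rose, including Tpi1 (21.9-fold) and Pgk1 (7.93-fold), as did 13 of 15 cholesterol synthesis genes, including Idi1 (8.29-fold) and Hmgcs1 (5.35-fold). The amino acid list had 12 of 17 members higher, such as the serine pathway enzymes Shmt2 (7.62-fold) and Psat1 (7.24-fold). In the TH2 list 10 of 17 genes rose and none fell, among them the TH2 chemokine receptors Ccr8 (33.8-fold) and Ccr4 (29.5-fold), the factor Nfil3 (32.3-fold) and the TH2 master regulator Gata3 (3.92-fold). Among costimulatory and inhibitory receptors 9 of 16 rose, with Tnfrsf4 up 15.96-fold and Ctla4 up 9.33-fold, and 1, Cd27, fell 8.06-fold. The naive and quiescence list had 13 of 15 members lower, among them Btg2 (11.9-fold), the lymph node homing receptor Ccr7 (5.01-fold) and Il6ra (5.18-fold). The interferon list had 11 of 16 lower, among them Irf7 (5.81-fold) and the viral RNA sensor Ddx58 (8.34-fold).

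Adjusted over the list alone, the counts of these lists became 13 higher and 1 lower in the amino acid list, 10 higher in the receptor list and 14 lower in the naive list, and were otherwise the same. Camera gave adjusted p = 1.44e-27 for mitosis, 1.36e-20 for DNA replication, 1.25e-14 for glycolysis, 5.88e-11 for cholesterol, 4.9e-07 for amino acids, 3.73e-06 for TH2, 0.000413 for the receptors, 4.56e-11 for the naive list and 4.66e-05 for interferon, all kept with an estimated correlation. The regulatory T cell list, to which Il2ra belongs, was also shifted up (7 of 11 rose, camera adjusted p = 0.00043). Its 1 falling member was Foxp3, the regulatory T cell factor, chosen in activation contrasts after its values were seen (71.5 ± 4.05 to 42.4 ± 0.822, adjusted p = 7.73e-05). The chaperone list shifted up (12 of 16 rose, 2 fell, camera adjusted p = 6.99e-05, adjusted p = 0.0667 with an estimated correlation). T cell identity genes shifted down, with 8 of 10 lower including the receptor chain Cd3g (3.22-fold; camera adjusted p = 0.00101, adjusted p = 0.13 with an estimated correlation). The list of AP-1, IRF and NFAT factors went both ways, 6 higher and 8 lower of 19, with Jun down 13.9-fold. Of 49 measured markers of other cell types, 11 fell, Ctss furthest (5.69-fold), and 1, H2-Ab1, rose (2.87-fold). In all, 3934 genes were higher and 4083 lower at day 2 (limma, Benjamini-Hochberg), 2000 and 877 of them by at least 2-fold. The median gene changed by -0.106 on the log2 scale, a value that renormalization moved by 0.136 (cyclic loess) or 0.142 (quantile), so folds of under about that size have no firm sign.

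At 4 days with 10 ng/ml, Il2ra stood 231-fold (95% CI 171 to 312) above naive WT cells, Lif 141-fold, and the metal-binding protein Mt2 185-fold (95% CI 121 to 282) at 2121 ± 357. The cytokines Il24 (98.1-fold), Il10 (77.03-fold) and Il21 (57.9-fold) and the inhibitory receptor Ctla4 (56.8-fold, to 2895 ± 569) rose, as did Irf4 (40.6-fold), Batf (11.9-fold) and Batf3 (4.74-fold (95% CI 3.61 to 6.205)). Ifi203, an interferon-inducible gene, fell 75.7-fold (95% CI 50.9 to 113) from 1071 ± 163 to 14.1 ± 2.24, and Ms4a4b 70.8-fold. Folds against levels this close to the array background understate the change.

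The TH2 list had 12 of 17 genes higher, with Ccr4 up 38.6-fold, and 1 lower (camera adjusted p = 9.49e-10). The receptor list had 11 of 16 higher and 1 lower (camera adjusted p = 8.17e-07). The effector regulator list had 9 of 13 higher and 2 lower (camera adjusted p = 6.26e-06), with Hif1a, a regulator of the oxygen response, up 7.96-fold and the factor Tox down 11.1-fold. AP-1, IRF and NFAT factors again split into 10 higher and 8 lower, with Fosl2 up 9.53-fold and Atf3 up 11.5-fold. All 15 mitosis genes (Top2a 40.04-fold, 8.78-fold as the mean of its probe sets), all 17 DNA replication genes and all 12 glycolysis genes (Pgk1 11.2-fold) were higher, with camera adjusted p = 2.02e-27, 1.11e-13 and 2.72e-17. Cholesterol genes rose in 13 of 15 (Fdft1 5.57-fold, camera adjusted p = 1.04e-10) and amino acid genes in 15 of 17 (camera adjusted p = 3.43e-09). The naive list fell in 12 of 15 (camera adjusted p = 3.87e-09), with Foxp1, a factor of T cell quiescence, down 8.01-fold and S1pr1 down 8.92-fold. Adjusted over the list alone, these counts were 4 lower in the receptor list, 3 lower in the effector regulator list and 14 higher in the cholesterol list, and otherwise the same.

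Further lists called were the regulatory T cell list (6 of 11 rose and 1, Foxp3, fell to 34.3 ± 5.52, adjusted p = 7.16e-07; camera adjusted p = 0.000199), the T follicular helper list (6 of 11 rose, 1 fell, 6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0199), the chaperone list (11 of 16 rose, 2 fell, camera adjusted p = 3.9e-05, adjusted p = 0.0541 with an estimated correlation) and the interferon list (9 of 16 fell, 1 rose, camera adjusted p = 0.00106, adjusted p = 0.0987 with an estimated correlation). The interleukin-12 receptor chain Il12rb2, of the TH1 list, rose 20.9-fold. Among ribosomal protein genes Rps2 rose 1.46-fold. These genes shifted up as a list (8 of 15 rose, camera adjusted p = 0.00106, adjusted p = 0.274 with an estimated correlation). Under both renormalizations the list lay nearly level with the remaining genes. Among markers of antigen-presenting cells, H2-Ab1, a major histocompatibility complex class II beta chain, rose 26.1-fold to 777 ± 162, while the class II genes H2-Aa and H2-Eb1 read 17.1 ± 2.53 and 28.1 ± 1.19 and Cd74 38.2 ± 3.68. Another 13 markers of other cell types fell, Ctss furthest (7.31-fold). The contrast called 3677 genes higher and 3585 lower, 1645 and 800 of them by at least 2-fold. Renormalization moved the median gene by 0.128 (cyclic loess) and 0.119 (quantile). T follicular helper markers lost the call with the filter on dim genes (adjusted p = 0.443) (over alternatives 0.00812 to 0.443). Rps2 lost the call under cyclic loess (adjusted p = 0.0503) and under quantile normalization (0.0758) (over alternatives 2.94e-07 to 0.0758). Ribosomal protein genes lost the call under cyclic loess (adjusted p = 0.775) and under quantile normalization (0.995) (over alternatives 2.23e-05 to 0.995).

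Most genes called in both genotypes at day 2 changed in the same direction in DKO as in WT cells. Il2ra rose 135-fold (95% CI 99.8 to 182) to 1517 ± 123 at day 2, Irf4 rose 22.3-fold, and Batf (log2 0.05 ± 0.16, adjusted p = 0.867) and Batf3 (0.05 ± 0.19, adjusted p = 0.902) did not pass. The mitotic genes Mki67, Top2a and Kif11 rose 49.6-fold, 38.2-fold (11.4-fold as the mean of its probe sets) and 43.95-fold. All 15 mitosis and all 17 DNA replication genes rose (camera adjusted p = 1.01e-33 and 1.19e-22), 11 of 12 glycolysis genes did (camera adjusted p = 2.53e-11), with Tpi1 up 13-fold. Of the naive list, 13 of 15 genes fell (camera adjusted p = 3.04e-12), with S1pr1 down 11.4-fold. Interferon genes fell in 10 of 16 (camera adjusted p = 3.63e-08), among them the interferon-inducible GTPase Iigp1 (4.13-fold), and Samd9l, outside the list, fell 46.3-fold. The TH2 list was higher in 4 of 17 and lower in 1 (camera adjusted p = 0.0221, adjusted p = 0.0712 with an estimated correlation), with Ccr8 up 16.7-fold, Ccr4 14-fold and Gata3 2.61-fold, and the effector regulator Bhlhe40 rose 5.04-fold.

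Further lists shifted up in DKO cells were the regulatory T cell markers (7 of 11 rose and 1, Foxp3, fell; camera adjusted p = 0.000217), the receptors (10 of 16 rose, 2 fell, camera adjusted p = 0.00016), the cholesterol genes (11 of 15, camera adjusted p = 1.43e-08, adjusted p = 0.0555 with an estimated correlation), the amino acid genes (10 of 17, camera adjusted p = 2.04e-05) and the chaperones (10 of 16 rose, 4 fell, camera adjusted p = 0.00465, adjusted p = 0.21 with an estimated correlation). Foxp3 read 83.3 ± 5.53 and 64.1 ± 2.22 (adjusted p = 0.0404) and lost the call under 3 settings (adjusted p = 0.0946 with cyclic loess, 0.0872 quantile, 0.059 trend) and without each of the 6 arrays but DKO day 0 replicate 3 (adjusted p from 0.0265 to 0.134 over alternatives). T cell identity genes shifted down (6 of 10, camera adjusted p = 0.00269, adjusted p = 0.206 with an estimated correlation). Adjusted over the list alone, 8 regulatory, 12 cholesterol and 11 chaperone genes were higher and 11 interferon genes lower, with the remaining counts unmoved. Of the markers of other cell types, 7 fell, Ctss furthest (2.75-fold), and 2 rose, Cd74 furthest (2.78-fold). The contrast called 3045 genes higher and 2654 lower, 1322 and 802 of them by at least 2-fold. Between the genotypes, 4708 genes were called in both activation contrasts, 4693 in the same direction and 15 in opposite directions. Chaperones lost the call with the filter on dim genes (adjusted p = 0.0609), under cyclic loess (0.0792) and under quantile normalization (0.133) (over alternatives 0.00096 to 0.21).

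A test of the difference in activation between genotypes called Il4, Il10, Il13 and Il24. Il4 rose from 21.2 ± 3.08 to 229 ± 8.77 in WT cells and read 18.1 ± 1.93 and 23.3 ± 3.23 in DKO cells, a difference of -3.08 ± 0.50 on the log2 scale (adjusted p = 0.00191). The difference was -2.96 ± 0.37 for Il10 (adjusted p = 8.85e-05) and -2.30 ± 0.36 for Bhlhe40 (adjusted p = 0.00147), besides -2.36 ± 0.22 for Batf itself (adjusted p = 2.67e-06). In the other direction, Ms4a4b fell less in DKO cells, from 717 ± 51.4 to 129.7 ± 27.8, than in WT cells, from 657 ± 64.7 to 17.2 ± 10.2 (difference 2.92 ± 0.43, adjusted p = 0.00078). Irf4 (-0.65 ± 0.30, adjusted p = 0.321) and Batf3 (-0.17 ± 0.27, adjusted p = 0.798) did not pass.

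Further genes responded less in DKO cells: Il24 (-3.56 ± 0.50), Inhba, the activin A subunit (-3.13 ± 0.37), the interleukin-12 receptor chain Il12rb1 (-1.34 ± 0.19) and Ccr4 (-1.08 ± 0.19). Single arrays ended the calls of another 6 genes: Il13 (-2.25 ± 0.49, adjusted p = 0.0201), Ctla4 (-1.64 ± 0.37, 0.0286), the hexokinase Hk2 (-1.43 ± 0.33, 0.0304), the glucose transporter Slc2a3 (-1.59 ± 0.34, 0.0193), Ccr7 (1.01 ± 0.25, 0.0447) and the naive gene Dapl1 (2.05 ± 0.51, 0.0481). Il13 lost the call with every probe set (adjusted p = 0.0791). Il13 also lost it without WT day 2 replicate 3 (adjusted p = 0.0562), without DKO day 0 replicate 2 (0.0513) and without DKO day 2 replicate 3 (0.0513) (over alternatives 0.00118 to 0.0791). Ctla4 lost the call with every probe set (adjusted p = 0.0983), under cyclic loess (0.0517), under quantile normalization (0.0553) and with the compared groups alone (0.0877). Ctla4 also lost it without WT day 0 replicate 3 (adjusted p = 0.0736), without WT day 2 replicate 1 (0.091) or 2 (0.102), without DKO day 0 replicate 2 (0.0852) or 3 (0.0792) and without DKO day 2 replicate 3 (0.0812) (over alternatives 0.000623 to 0.102). Hk2 lost the call with every probe set (adjusted p = 0.0969) and under quantile normalization (0.055). Hk2 also lost it without each of the 12 arrays but WT day 0 replicate 1, WT day 2 replicate 3, DKO day 0 replicate 2 and DKO day 2 replicate 1 and 3 (adjusted p up to 0.0828) (over alternatives 0.00636 to 0.0969). Slc2a3 lost the call with every probe set (adjusted p = 0.0695) and with the compared groups alone (0.0505). Slc2a3 also lost it without WT day 0 replicate 1 (adjusted p = 0.0505), without WT day 2 replicate 1 (0.0673) or 2 (0.07), without DKO day 0 replicate 2 (0.0569) and without DKO day 2 replicate 3 (0.0582) (over alternatives 0.000621 to 0.07). Ccr7 lost the call with every probe set (adjusted p = 0.111), with the compared groups alone (0.058) and without the 2 WT arrays (0.118). Ccr7 also lost it without each of the 12 arrays but WT day 0 replicate 3, WT day 2 replicate 1 and DKO day 2 replicate 3 (adjusted p up to 0.123) (over alternatives 0.02 to 0.123). Dapl1 lost the call with every probe set (adjusted p = 0.139), with trend and robust moderation (0.0869), with array weights (0.0505) and without the 2 WT arrays (0.0824). Dapl1 also lost it without each of the 12 arrays but WT day 0 replicate 3 and DKO day 2 replicate 3 (adjusted p up to 0.129) (over alternatives 0.0116 to 0.139).

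The TH2 list as a whole responded less in DKO cells, with 5 of 17 members called and 8 adjusted over the list alone (camera adjusted p = 2.02e-09). Glycolysis genes were called in 4 of 12, or 10 adjusted over the list alone (camera adjusted p = 6.57e-12, adjusted p = 0.0504 with an estimated correlation). The camera calls of the remaining lists were lost with an estimated correlation: effector regulators (3 of 13, 2 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0204, adjusted p = 0.0845 with an estimated correlation), naive genes (2 of 15 higher, 3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.03, adjusted p = 0.468 with an estimated correlation), DNA replication (0 of 17, 0 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.000137, adjusted p = 0.247 with an estimated correlation), cholesterol (1 of 15, 0 higher and 2 lower adjusted over the list alone, camera adjusted p = 2.73e-05, adjusted p = 0.218 with an estimated correlation), amino acids (2 of 17, 0 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.000101, adjusted p = 0.0981 with an estimated correlation) and chaperones (1 of 16, 0 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.000847, adjusted p = 0.214 with an estimated correlation). Of markers of other cell types Ctss (1.05 ± 0.26) and Siglech (0.75 ± 0.16) differed, calls that ended under 4 settings each and also, for Ctss, without each of the 12 arrays but DKO day 2 replicate 2 (adjusted p from 0.0132 to 0.126) and, for Siglech, without WT day 0 replicate 1, WT day 2 replicate 2 or 3, DKO day 0 replicate 2 or 3 or DKO day 2 replicate 2 (from 0.0105 to 0.0862). In all 61 genes differed upward and 148 downward, 209 together. Leaving out single arrays moved this total over 1.5 times in 4 cases, to 117 without WT day 2 replicate 1, 98 without WT day 2 replicate 2, 132 without DKO day 0 replicate 2 and 132 without DKO day 2 replicate 3. Effector regulators lost the call with the filter on dim genes (adjusted p = 0.193), under cyclic loess (0.0705) and with the compared groups alone (0.0544) (over alternatives 0.00923 to 0.193). Naive genes lost the call without WT day 0 replicate 2 (adjusted p = 0.108), without WT day 2 replicate 2 (0.0787), without DKO day 0 replicate 1 (0.0906) and without DKO day 2 replicate 1 (0.174) (over alternatives 0.00022 to 0.468). Chaperones lost the call with the filter on dim genes (adjusted p = 0.0511) and under cyclic loess (0.115) (over alternatives 0.000234 to 0.214).

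Before stimulation few genes passed between the genotypes. Batf was 4.31-fold (95% CI 3.45 to 5.38) lower in DKO cells, and 13 genes passed, Batf among them, 11 higher and 2 lower. Iigp1 was 3.72-fold (95% CI 2.68 to 5.15) higher at 123 ± 31.3 against 33.4 ± 11.3, Cd200r4, a receptor of the CD200 receptor family, 2.11-fold (95% CI 1.74 to 2.55) higher, and Il2rb, the beta chain of the interleukin-2 receptor, 1.93-fold (95% CI 1.57 to 2.36) higher. Tnfsf8, the CD30 ligand (1.99-fold (95% CI 1.52 to 2.597) higher), the NF-kB cofactor Bcl3 (1.72-fold (95% CI 1.41 to 2.09) higher) and the neuropeptide Calcb (1.74-fold (95% CI 1.398 to 2.15) lower) passed too. Batf3 (log2 difference -0.25 ± 0.19, adjusted p = 0.852) and Irf4 (-0.02 ± 0.21, adjusted p = 0.993) did not pass. The lists of AP-1, IRF and NFAT factors (1 of 19, the knocked-out Batf, fell, camera adjusted p = 0.0346, adjusted p = 0.262 with an estimated correlation) and DNA replication (0 of 17 rose, 1 adjusted over the list alone, camera adjusted p = 0.0204, adjusted p = 0.766 with an estimated correlation) were called by camera. The total of 13 became 7 without WT day 0 replicate 2, 6 without DKO day 0 replicate 1, 4 without DKO day 0 replicate 2, 4 under cyclic loess and 2 when the 6 day 0 arrays were fitted alone. Tnfsf8 lost the call with every probe set (adjusted p = 0.106), under cyclic loess (0.0919), with array weights (0.0625) and with the compared groups alone (0.264). Tnfsf8 also lost it without each of the 6 arrays but WT day 0 replicate 3 (adjusted p up to 0.174) (over alternatives 0.00511 to 0.264). Bcl3 lost the call with every probe set (adjusted p = 0.0584), under cyclic loess (0.0611), with array weights (0.0625) and with the compared groups alone (0.479). Bcl3 also lost it without each of the 6 arrays but WT day 0 replicate 1 and DKO day 0 replicate 3 (adjusted p up to 0.154) (over alternatives 0.0043 to 0.479). Calcb lost the call with every probe set (adjusted p = 0.0884), under cyclic loess (0.0611), with the replicate number as a block (0.0544), with array weights (0.0647), with the compared groups alone (0.381) and without the 2 WT arrays (0.0621). Calcb also lost it without each of the 6 arrays but DKO day 0 replicate 3 (adjusted p up to 0.245) (over alternatives 0.021 to 0.381). The AP-1 list lost the call with every probe set (adjusted p = 0.0995), with the mean of probe sets (0.0655), with the compared groups alone (0.094) and without Batf and Batf3 in the list (0.544). The AP-1 list also lost it without each of the 6 arrays but WT day 0 replicate 1 and DKO day 0 replicate 3 (adjusted p up to 0.356) (over alternatives 0.000767 to 0.544). DNA replication genes lost the call with the filter on dim genes (adjusted p = 0.124), with the mean of probe sets (0.0655), under cyclic loess (0.221) and with the compared groups alone (0.0544). DNA replication genes also lost it without WT day 0 replicate 3 (adjusted p = 0.0909) and without DKO day 0 replicate 1 (0.0949) (over alternatives 0.00455 to 0.766). Iigp1 lost the call with the compared groups alone (adjusted p = 0.0541) (over alternatives 3.83e-05 to 0.0541). Cd200r4 lost the call with the compared groups alone (adjusted p = 0.0969) (over alternatives 7.34e-05 to 0.0969). Il2rb lost the call with the compared groups alone (adjusted p = 0.381) (over alternatives 0.00114 to 0.381).

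After 2 days, Il4 was 9.86-fold (95% CI 5.95 to 16.3) lower in DKO cells, at 23.3 ± 3.23 against 229 ± 8.77, Il24 10.98-fold (95% CI 6.61 to 18.2) lower, Il10 6.65-fold and Il13 5.03-fold. Nts, the neuropeptide neurotensin, was 12.3-fold lower and Inhba, the activin A subunit, 7.96-fold lower. Higher in DKO cells were the naive-cell gene Ms4a4b (8.25-fold (95% CI 5.32 to 12.8)), its relative Ms4a6b (3.65-fold), the growth factor Csf1 (3.48-fold), Ccr7 (2.13-fold), Cd27 (2.001-fold) and Tox (1.86-fold).

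In the TH2 list 7 of 17 genes were lower and none higher (8 lower adjusted over the list alone, camera adjusted p = 1.42e-12), with Ccr4 down 2.35-fold. Glycolysis genes were lower in 9 of 12 (11 adjusted over the list alone, camera adjusted p = 2.88e-16), including hexokinase Hk2 (2.99-fold) and the glucose transporter Slc2a3 (2.89-fold). Amino acid genes were lower in 3 of 17 (10 adjusted over the list alone, camera adjusted p = 1.4e-07). Effector regulators split into 2 higher and 4 lower of 13, with Bhlhe40 down 4.92-fold (2 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0342, adjusted p = 0.0743 with an estimated correlation). Among costimulatory and inhibitory receptors Tnfrsf4 was 2.05-fold lower and Ctla4 2.44-fold lower, and of the follicular helper list Cd200 was 2.25-fold lower. Of the TH1 list Il12rb1, an interleukin-12 receptor chain, was 2.48-fold lower. T cell identity genes were higher in 3 of 10 (camera adjusted p = 0.00571, adjusted p = 0.265 with an estimated correlation), including Cd3g (1.603-fold). Naive genes were higher in 3 of 15 (7 adjusted over the list alone, camera adjusted p = 0.00571, adjusted p = 0.384 with an estimated correlation). Of genes on the lists for other cell types, H2-Ab1 was 2.62-fold lower, and Ctss (2.64-fold), Cd74 (2.15-fold) and Cd79b (1.66-fold) were higher. Effector regulators lost the call with the filter on dim genes (adjusted p = 0.261), with the mean of probe sets (0.0838), under cyclic loess (0.109) and with the compared groups alone (0.0892). Effector regulators also lost it without each of the 6 arrays but WT day 2 replicate 3 and DKO day 2 replicate 3 (adjusted p up to 0.102) (over alternatives 0.0161 to 0.261). Ctla4 lost the call with the compared groups alone (adjusted p = 0.0586). Ctla4 also lost it without WT day 2 replicate 1 (adjusted p = 0.0542) or 2 (0.0607) (over alternatives 5.09e-05 to 0.0607). Cd200 lost the call with every probe set (adjusted p = 0.0546). Cd200 also lost it without WT day 2 replicate 3 (adjusted p = 0.0763) and without DKO day 2 replicate 1 (0.0529) or 3 (0.059) (over alternatives 0.00335 to 0.0763). T cell identity genes lost the call without DKO day 2 replicate 1 (adjusted p = 0.0698) (over alternatives 1.28e-05 to 0.265). Naive genes lost the call without DKO day 2 replicate 1 (adjusted p = 0.0848) (over alternatives 4.65e-05 to 0.384). Cd79b lost the call with every probe set (adjusted p = 0.0717), under cyclic loess (0.0719), under quantile normalization (0.0579) and without the 2 WT arrays (0.0758). Cd79b also lost it without each of the 6 arrays but DKO day 2 replicate 2 (adjusted p up to 0.157) (over alternatives 0.0201 to 0.157). Cd74 lost the call with the compared groups alone (adjusted p = 0.0821) (over alternatives 0.000989 to 0.0821).

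Camera also called, downward, AP-1, IRF and NFAT factors (3 of 19 fell, the knocked-out Batf among them, 4 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.00571, adjusted p = 0.0503 with an estimated correlation), cholesterol (3 of 15 fell, 10 adjusted over the list alone, camera adjusted p = 2.78e-09, adjusted p = 0.0734 with an estimated correlation), DNA replication (0 of 17 fell, camera adjusted p = 0.00624, adjusted p = 0.401 with an estimated correlation), chaperones (0 of 16 fell, 0 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00157, adjusted p = 0.161 with an estimated correlation) and, upward, B cell markers (1 of 9 rose, camera adjusted p = 0.0317, adjusted p = 0.0743 with an estimated correlation). Batf was 22.1-fold lower, Batf3 did not pass (adjusted p = 0.26), and Irf4 was -0.67 on the log2 scale without passing (adjusted p = 0.0965), though it passed with array weights (0.0484) and when the 6 day 2 arrays were fitted alone (0.0223). The contrast called 206 genes higher and 335 lower, 52 and 105 by at least 2-fold. The total of 541 became 314 without WT day 2 replicate 1, 298 without WT day 2 replicate 2 and 315 without DKO day 2 replicate 3. The AP-1 list lost the call with the filter on dim genes (adjusted p = 0.261) and without Batf and Batf3 in the list (0.232) (over alternatives 0.00477 to 0.261). DNA replication genes lost the call with the filter on dim genes (adjusted p = 0.157), under cyclic loess (0.222) and under quantile normalization (0.144) (over alternatives 0.0015 to 0.401). Chaperones lost the call with the filter on dim genes (adjusted p = 0.0573) and under cyclic loess (0.0942) (over alternatives 0.000531 to 0.161). B cell markers lost the call under cyclic loess (adjusted p = 0.169) and under quantile normalization (0.118). B cell markers also lost it without WT day 2 replicate 2 (adjusted p = 0.065) and without DKO day 2 replicate 2 (0.0593) (over alternatives 0.0184 to 0.169).

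At 4 days with 2.2 ng/ml, Cd24a, a surface glycoprotein, was 71.05-fold (95% CI 42.5 to 119) lower in DKO cells, at 21.2 ± 14.3 against 1294 ± 161, Il10 47.1-fold (95% CI 32.5 to 68.2) lower and Lif 19.8-fold lower. Cyp11a1, the enzyme that starts steroid hormone synthesis, was 17.2-fold lower, the opioid precursor Penk 15.1-fold, the cytotoxic protease Gzmb 10.7-fold and Epas1, an oxygen-response factor related to Hif1a, 10.3-fold. Higher in DKO cells were Foxp3, at 237 ± 26.5 against 65.9 ± 14.7 (3.64-fold (95% CI 2.99 to 4.43)), Arhgap20 (5.84-fold), the bacterial peptidoglycan sensor Nod1 (5.27-fold), Iigp1 (4.48-fold) and the chemokine receptor Ccr9 (4.09-fold).

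All 12 glycolysis genes were lower in DKO cells (camera adjusted p = 1.8e-30), with Slc2a3 down 4.25-fold and Tpi1 2.68-fold. So were 11 of 15 cholesterol genes (14 adjusted over the list alone, camera adjusted p = 1.35e-18), with Nsdhl down 2.23-fold. Effector regulators were lower in 7 of 13 (camera adjusted p = 2.42e-11), including Prdm1, which encodes Blimp-1 (4.92-fold), Bhlhe40 (6.17-fold) and Hif1a (1.99-fold). The TH2 list was lower in 8 of 17 (9 adjusted over the list alone, camera adjusted p = 1.39e-14), with Ccr8 down 3.92-fold and Gata3 2.26-fold. The receptors were lower in 7 of 16 with 2 higher (3 higher and 8 lower adjusted over the list alone; camera adjusted p = 9.33e-05), including Ctla4 (3.95-fold), Tigit (3.44-fold) and Icos (1.84-fold). Early T cell receptor-induced genes were higher in 5 of 16 (camera adjusted p = 2.52e-05, adjusted p = 0.104 with an estimated correlation), among them the NF-kB subunit Rel (1.87-fold), and Ccr7, of the naive list, was 2.095-fold higher.

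The mitosis list shifted down with 1 of 15 members called and 5 adjusted over the list alone (camera adjusted p = 1.29e-07). Regulatory T cell markers shifted up (4 of 11 rose and 2, Il2ra (1.91-fold) and Ctla4, fell, 5 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0355, adjusted p = 0.0756 with an estimated correlation). Amino acid genes (3 of 17 fell, 0 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.00134, adjusted p = 0.104 with an estimated correlation) and chaperones (3 of 16 fell, 6 adjusted over the list alone, camera adjusted p = 4.21e-05, adjusted p = 0.0756 with an estimated correlation) shifted down, as did dendritic cell markers (2 of 9 fell, 0 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.00251, adjusted p = 0.0895 with an estimated correlation), among them H2-Ab1 (4.18-fold), while the macrophage marker Ctss was 1.63-fold higher. Batf was 47.2-fold lower, while Batf3 (adjusted p = 0.695) and Irf4 (log2 -0.12, adjusted p = 0.923) did not pass. The contrast called 329 genes higher and 410 lower, 72 and 150 by at least 2-fold. The total of 739 became 489 without DKO 2.2 ng/ml replicate 2, 496 without the 2 WT arrays, and 462 when the 6 arrays were fitted alone. Il2ra lost the call without the 2 WT arrays (adjusted p = 0.0891). Il2ra also lost it without WT 2.2 ng/ml replicate 3 (adjusted p = 0.0746) and without DKO 2.2 ng/ml replicate 1 (0.0561) (over alternatives 0.00651 to 0.0891). Regulatory T cell markers lost the call with the filter on dim genes (adjusted p = 0.141) and with the compared groups alone (0.0563). Regulatory T cell markers also lost it without WT 2.2 ng/ml replicate 1 (adjusted p = 0.0558) and without DKO 2.2 ng/ml replicate 2 (0.102) (over alternatives 0.0148 to 0.141). Ctss lost the call with every probe set (adjusted p = 0.0721), with the compared groups alone (0.0692) and without the 2 WT arrays (0.248). Ctss also lost it without WT 2.2 ng/ml replicate 3 (adjusted p = 0.219) and without DKO 2.2 ng/ml replicate 2 (0.101) or 3 (0.123) (over alternatives 0.0188 to 0.248).

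At 10 ng/ml more genes were called between the genotypes than in any other state, and the TH2 and effector regulator lists were lower in DKO cells. Lilr4b and Lilrb4a, a pair of closely related immunoglobulin-like receptor genes whose probes may not separate them, were 207-fold (95% CI 144 to 297) and 111-fold lower in DKO cells, from 1982 ± 425 and 1459 ± 447 in WT cells to 9.54 ± 1.83 and 12.8 ± 1.85. Il24 was 94.2-fold lower, Mt2 93.2-fold (141-fold without DKO replicate 3), Il10 66.7-fold, Il21 58.3-fold, Inhba 53.9-fold and Il13 36.2-fold (95% CI 22.1 to 59.1). Csn2, the milk protein beta-casein, was 69.7-fold (95% CI 44.9 to 108) higher in DKO cells at 1092 ± 358 against 15.1 ± 1.84, and Tox was 13-fold higher, the T cell receptor adaptor Trat1 11.3-fold, the naive gene Dapl1 9.36-fold and Csf1 8.502-fold.

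The TH2 list was lower in 11 of 17 and higher in 2 (2 higher and 12 lower adjusted over the list alone; camera adjusted p = 1.66e-13). The TH1 list was lower in 7 of 15 and higher in 2 (camera adjusted p = 0.000682), with Il12rb2 down 12.1-fold. The receptor list was lower in 7 of 16 and higher in 3 (3 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.00256), with Ctla4 down 12.8-fold, Tnfrsf8 11.5-fold and Tigit 6.21-fold, and Icos up 1.85-fold. AP-1, IRF and NFAT factors were lower in 7 of 19 and higher in 4 (4 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.00267), including the knocked-out Batf and Batf3 and Fosl2 (8.801-fold), and effector regulators in 8 of 13, with 2 higher (camera adjusted p = 4.11e-06), including Hif1a (5.27-fold) and Prdm1 (5.26-fold). The ligand-activated factor Ahr was 10.2-fold lower. Early T cell receptor-induced genes were higher in 6 of 16 and lower in 2 (9 adjusted over the list alone, camera adjusted p = 0.000129, adjusted p = 0.159 with an estimated correlation), including Nr4a3 (7.16-fold) and Cd69 (5.57-fold), and Foxp1 was 3.53-fold higher. The AP-1 list lost the call without Batf and Batf3 in the list (adjusted p = 0.183) (over alternatives 0.00157 to 0.183).

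At this dose mitosis genes were higher in DKO cells in 11 of 15 (14 adjusted over the list alone, camera adjusted p = 3.05e-10), with Kif11 up 2.16-fold. DNA replication genes were higher in 12 of 17 (13 adjusted over the list alone, camera adjusted p = 3.58e-09, adjusted p = 0.0535 with an estimated correlation), with Tyms up 2.74-fold. Cholesterol genes were higher in 9 of 15 (11 adjusted over the list alone, camera adjusted p = 1.76e-07, adjusted p = 0.0881 with an estimated correlation), with Hmgcs1 up 2.16-fold and Idi1 2.299-fold. Glycolysis genes were lower in 3 of 12 (0 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0282, adjusted p = 0.412 with an estimated correlation) and chaperones in 2 of 16 (camera adjusted p = 0.0123, adjusted p = 0.255 with an estimated correlation). Of the markers of other cell types, Cd74 (4.85-fold), Cd79b (3.195-fold), Ctss (4.58-fold) and Hdc (4.05-fold) were higher in DKO cells and 2 were lower, H2-Ab1 furthest (3.397-fold), while the B cell genes Cd79a and Ms4a1 read 11.4 ± 0.968 and 6.17 ± 0.611 in these DKO cells and the myeloid genes Lyz2 and Itgax 7.05 ± 0.684 and 9.75 ± 1.71. No list of other cell types was called here. Glycolysis genes lost the call without WT 10 ng/ml replicate 1 (adjusted p = 0.077) or 3 (0.166) and without DKO 10 ng/ml replicate 1 (0.0709) (over alternatives 0.0012 to 0.412). Chaperones lost the call without DKO 10 ng/ml replicate 3 (adjusted p = 0.0677) (over alternatives 0.00224 to 0.255).

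Batf was 34.4-fold and Batf3 4.86-fold lower. Irf4 was -0.54 ± 0.21 on the log2 scale and did not pass (adjusted p = 0.112), but passed under cyclic loess (0.0358), with array weights (0.0409), when the 6 arrays were fitted alone (0.0148) and without the 2 WT arrays (0.0437). The contrast called 1331 genes higher and 1214 lower, 259 and 436 by at least 2-fold.

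**Figure D3:**
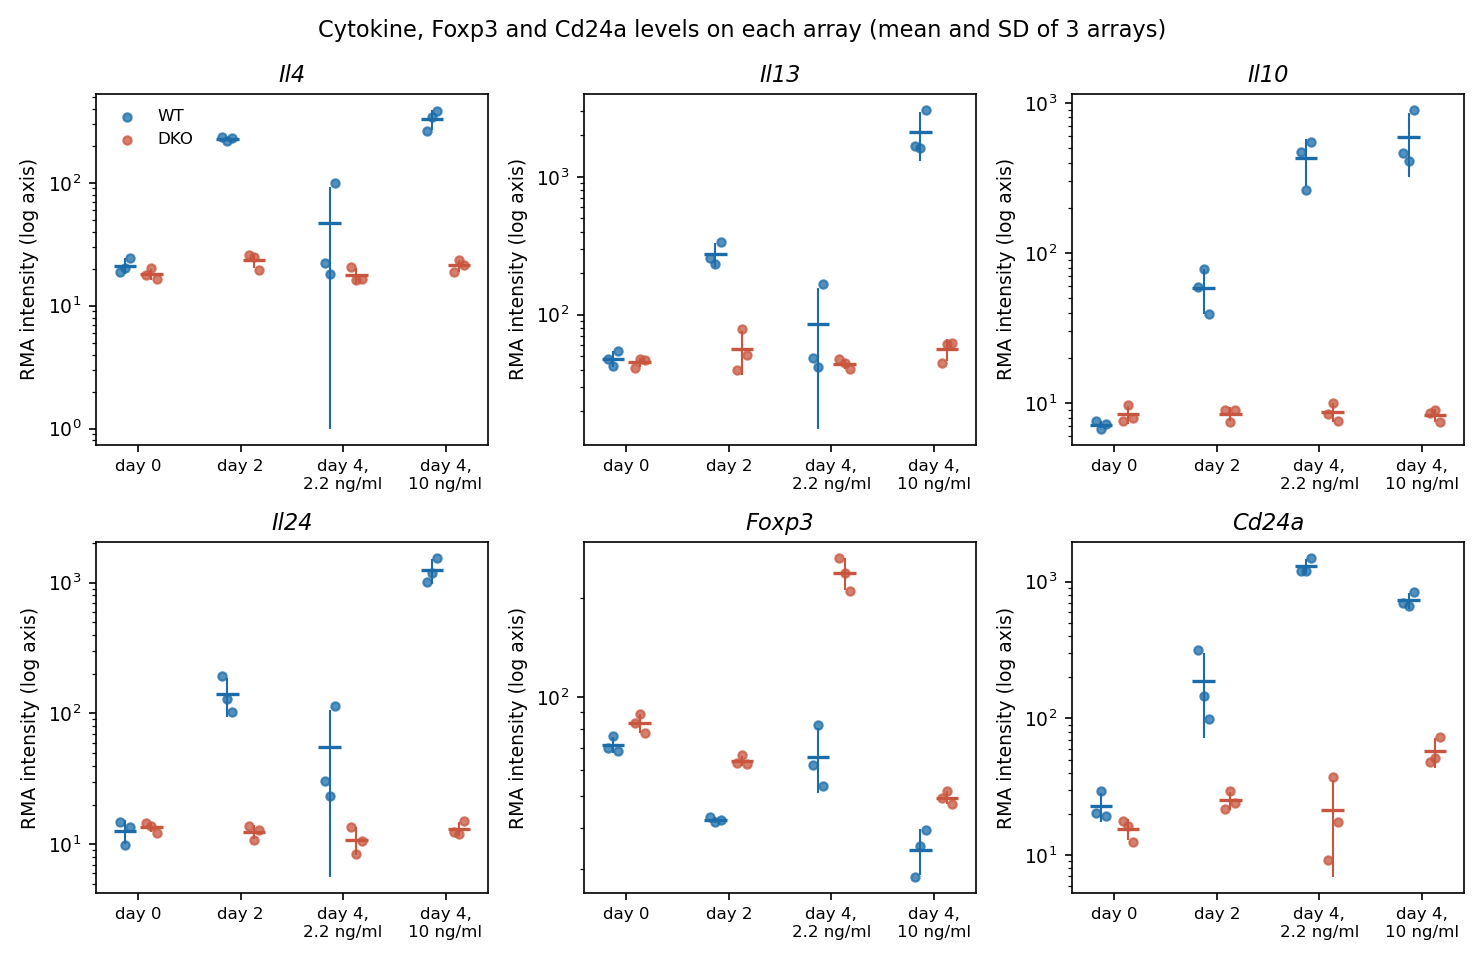
RMA intensity (y axis, log scale) of Il4, Il13, Il10, Il24, Foxp3 and Cd24a on each array by state (x axis), in WT (blue) and DKO (red); points are arrays, horizontal lines means and vertical lines SD of 3 arrays, ending at 1 for Il4 in WT at 2.2 ng/ml. In DKO cells the Il4 means run from 17.7 to 23.3, and Foxp3 is highest in DKO at 2.2 ng/ml, at 237.

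With 10 in place of 2.2 ng/ml of anti-CD3e, the TH2 list was higher and the mitosis list lower in WT cells at day 4. Mt2 rose 164-fold (95% CI 107 to 250.1), from 12.9 ± 1.89 to 2121 ± 357, its relative Mt1 37.2-fold, the cross-linking enzyme Tgm2 35.3-fold, Il13 28.9-fold (95% CI 17.7 to 47.2) and Il24 28.5-fold, or 44.8-fold and 46.2-fold without WT 2.2 ng/ml replicate 3. Irf4 rose 3.46-fold (95% CI 2.55 to 4.703) and Batf3 5.02-fold (95% CI 3.83 to 6.57), whereas Batf itself read 1509 ± 125 and 1595 ± 99.8 and did not pass (log2 0.08 ± 0.16, adjusted p = 0.827). Falling genes included Ms4a4b (29.1-fold), Trat1 (25.9-fold), Tox (13.4-fold), Dapl1 (10.9-fold) and Eomes, a T-box factor (10.4-fold).

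In the TH2 list 6 of 17 genes rose and 1 fell (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000134), with Il4 up 9.54-fold (16.3-fold without WT 2.2 ng/ml replicate 3) and Il5 4.92-fold. The receptors rose in 9 of 16 and fell in 3 (camera adjusted p = 0.00249), with Tigit up 5.19-fold and Tnfrsf9 4.58-fold, and Icos down 2.71-fold. AP-1, IRF and NFAT factors rose in 8 of 19 and fell in 3 (9 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.000557), with Atf3 up 12.1-fold and Fosl2 6.74-fold. Effector regulators rose in 6 of 13 and fell in 3 (camera adjusted p = 0.0257), with Bhlhe40 up 3.53-fold and Hif1a 2.41-fold. Ahr rose 10.8-fold, the follicular helper cytokine Il21 14.7-fold, Il12rb2 15.2-fold and the chemokine Ccl5 10.7-fold, while Gzmb fell 4.55-fold and Foxp1 3.999-fold. Effector regulators lost the call with the filter on dim genes (adjusted p = 0.139). Effector regulators also lost it without WT 10 ng/ml replicate 3 (adjusted p = 0.0676) (over alternatives 0.00921 to 0.139).

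Glycolysis genes rose in 8 of 12 (9 adjusted over the list alone, camera adjusted p = 7.63e-08), with Slc2a3 up 3.51-fold, and amino acid genes in 8 of 17, with 1 lower (8 higher and 2 lower adjusted over the list alone, camera adjusted p = 5.83e-05). Mitosis genes fell in 10 of 15 (12 adjusted over the list alone, camera adjusted p = 2.58e-07), with Kif11 down 2.04-fold. DNA replication genes fell in 10 of 17 (11 adjusted over the list alone, camera adjusted p = 5.29e-07, adjusted p = 0.079 with an estimated correlation), with Tyms down 2.78-fold. Regulatory T cell markers (5 of 11 rose and 1, Foxp3, fell 1.91-fold; camera adjusted p = 0.0058), p53 targets (4 of 13 rose, 4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00546) and ribosomal protein genes (0 of 15 rose, camera adjusted p = 0.0058, adjusted p = 0.509 with an estimated correlation) shifted up. Of the markers of other cell types, H2-Ab1 rose 8.43-fold, and Ctss (3.32-fold), Cd74 (2.26-fold) and H2-Aa (1.65-fold) fell. The contrast called 1523 genes higher and 1499 lower, 524 and 252 by at least 2-fold, and 3022 together became 2466 without the 2 WT arrays. H2-Aa lost the call with the compared groups alone (adjusted p = 0.0534) (over alternatives 0.000307 to 0.0534).

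In DKO cells the cholesterol synthesis and glycolysis lists rose with dose. Scd1, a fatty acid desaturase, rose 113-fold (95% CI 61.98 to 205), from 9.46 ± 0.693 to 1077 ± 199.9, the desaturase Fads2 21.9-fold, Csn2 19.7-fold (13.02-fold without DKO 2.2 ng/ml replicate 1), the glycolytic enzyme Aldoc 14.3-fold and Egln3, an oxygen-sensing prolyl hydroxylase, 11.9-fold. Irf4 rose 2.59-fold (95% CI 1.903 to 3.51), while Batf3 did not pass (24.2 ± 2.87 and 29.8 ± 4.57, adjusted p = 0.463). Residual Batf signal was 1.45-fold higher at 10 ng/ml (32.2 ± 4.99 and 46.5 ± 4.87, adjusted p = 0.0307). The falls included Ms4a4b (17.96-fold (95% CI 11.6 to 27.9)), Eomes (13.03-fold), Arhgap20 (11.7-fold), S1pr1 (5.701-fold) and Foxp3, which fell 4.78-fold (95% CI 3.93 to 5.82) from 237 ± 26.5 to 49.4 ± 2.204. Batf lost the call with every probe set (adjusted p = 0.0588). Batf also lost it without each of the 6 arrays but DKO 2.2 ng/ml replicate 3 and DKO 10 ng/ml replicate 1 (adjusted p up to 0.184) (over alternatives 0.0184 to 0.184).

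All 15 cholesterol genes rose (camera adjusted p = 1.07e-31), including Hmgcs1 (3.36-fold) and Lss (3.71-fold). So did all 12 glycolysis genes (camera adjusted p = 1.01e-32), including Slc2a1 (4.82-fold) and Slc2a3 (6.68-fold). Amino acid genes rose in 11 of 17 (12 adjusted over the list alone, camera adjusted p = 1.78e-17), including asparagine synthetase Asns (4.77-fold) and Chac1 (5.73-fold). Mitosis genes rose in 6 of 15 (9 adjusted over the list alone, camera adjusted p = 3.13e-08). Effector regulators rose in 5 of 13 and fell in 2 (camera adjusted p = 0.00821), with Bhlhe40 up 9.45-fold and the Ikaros family factor Ikzf3 down 4.33-fold. Receptors rose in 5 of 16 and fell in 2 (8 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.000885), with Tnfrsf4 up 3.35-fold and Cd27 down 2.76-fold. Effector regulators lost the call with the filter on dim genes (adjusted p = 0.0662) (over alternatives 0.00243 to 0.0662).

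AP-1, IRF and NFAT factors rose in 6 of 19 and fell in 1 (8 adjusted over the list alone, camera adjusted p = 0.0014). The naive list fell in 6 of 15 (7 adjusted over the list alone, camera adjusted p = 2.44e-05, adjusted p = 0.142 with an estimated correlation), and T cell identity genes in 3 of 10 (0 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0462, adjusted p = 0.403 with an estimated correlation). The TH2 list was not called (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0731), with Ccr8 up 4.05-fold, Gata3 up 1.57-fold and Il4ra down 1.81-fold. Of the markers of other cell types, 5 rose and 1 fell, with H2-Ab1 (10.4-fold), Hdc (2.38-fold), Cd74 (2.28-fold) and Cd79b (2-fold) rising most. The contrast called 891 genes higher and 734 lower, 289 and 133 by at least 2-fold. The total of 1625 became 1058 without DKO 2.2 ng/ml replicate 1. T cell identity genes lost the call with the filter on dim genes (adjusted p = 0.0785) and with the compared groups alone (0.0696). T cell identity genes also lost it without each of the 6 arrays but DKO 2.2 ng/ml replicate 1 and DKO 10 ng/ml replicate 1 (adjusted p up to 0.076) (over alternatives 0.00202 to 0.403).

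**Figure D4:**
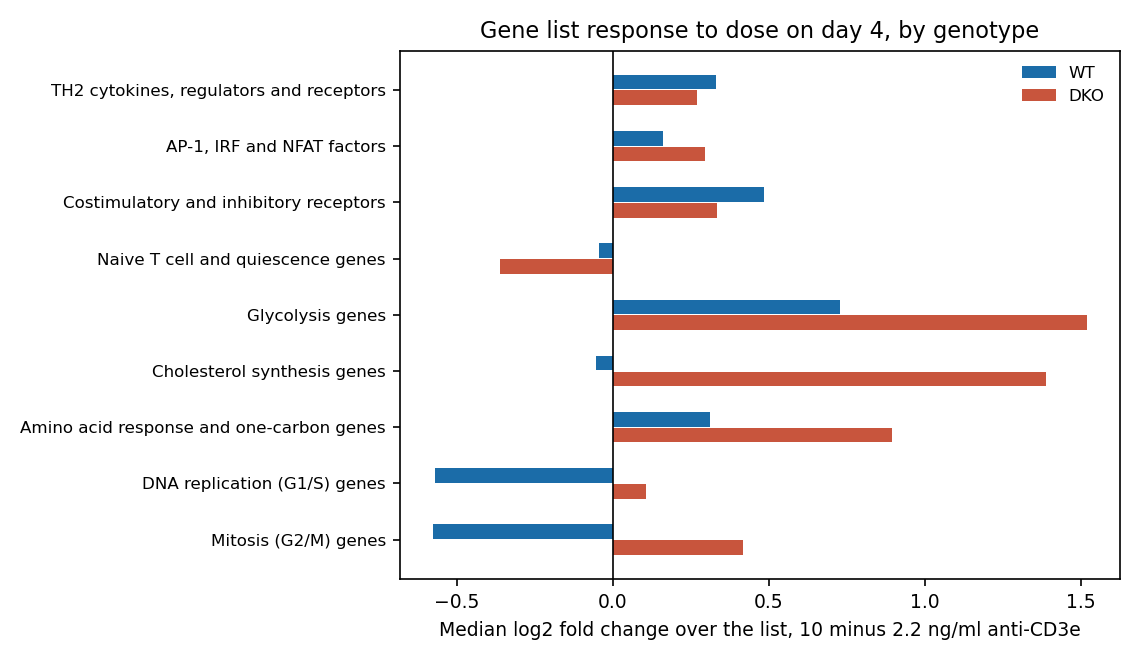
Median log2 fold change over each gene list (x axis) from 2.2 to 10 ng/ml anti-CD3e at day 4, in WT (blue bars) and DKO (red bars); a list median is drawn without error. The cholesterol list stands at -0.05 in WT (mean 0.0043, not called) and 1.39 in DKO, and the mitosis list at -0.57 and 0.42.

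The dose response was then compared between genotypes in one test, as the log2 response of DKO cells minus that of WT cells. It was -6.39 ± 0.42 for Mt2 (adjusted p = 5.38e-10), -4.68 ± 0.32 for Tgm2, -4.54 ± 0.50 for Il24, -4.52 ± 0.49 for Il13, -4.23 ± 0.28 for Il21, -2.98 ± 0.50 for Il4 (adjusted p = 0.000307) and -2.44 ± 0.34 for Il5. Without WT 2.2 ng/ml replicate 3 it was -5.24 for Il24, -5.15 for Il13 and -3.76 for Il4, and without DKO 10 ng/ml replicate 3 -6.98 for Mt2. Among receptors and factors it was -3.23 ± 0.29 for Il12rb2, -3.13 ± 0.24 for Ahr, -2.31 ± 0.24 for Fosl2, -2.03 ± 0.27 for Batf3, -1.70 ± 0.37 for Ctla4, -1.40 ± 0.16 for Hif1a and -1.33 ± 0.19 for Foxp3. For Trat1 it was 4.01 ± 0.37. For Tox the difference was 3.49 ± 0.21 (adjusted p = 1.43e-10), from 371 ± 57.5 to 27.7 ± 5.02 in WT cells and 427 ± 43.4 to 357 ± 39.6 in DKO cells. Icos fell from 1470.5 ± 202 to 540.4 ± 31.8 in WT cells and read 796 ± 55.97 and 1001 ± 68.6 in DKO cells, a difference of 1.77 ± 0.18. Irf4 (-0.42 ± 0.30, adjusted p = 0.558) and Batf (0.46 ± 0.22, adjusted p = 0.282) did not pass.

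Cholesterol genes responded more in DKO cells in 14 of 15 (15 adjusted over the list alone, camera adjusted p = 1.22e-20). Hmgcs1 read 332 ± 11.9 and 299 ± 14.8 in WT cells and 193 ± 11.3 and 647 ± 36.6 in DKO cells (difference 1.90 ± 0.19). The difference was 1.91 ± 0.27 for Nsdhl and for Scd1 it was 3.89 ± 0.59. Mitosis genes differed in the same direction in 14 of 15 (15 adjusted over the list alone, camera adjusted p = 1.27e-17), with Kif11 at 1.26 ± 0.16. DNA replication genes did so in 10 of 17 (12 adjusted over the list alone, camera adjusted p = 1.86e-09, adjusted p = 0.0593 with an estimated correlation), with Tyms at 1.57 ± 0.25. Glycolysis genes followed in 9 of 12 (10 adjusted over the list alone, camera adjusted p = 2.5e-10), with Slc2a1 at 1.32 ± 0.28, and amino acid genes in 4 of 17 (8 adjusted over the list alone, camera adjusted p = 0.000823, adjusted p = 0.112 with an estimated correlation). TH1 markers (4 of 15 lower, 1, Gzmb at 2.04 ± 0.38, higher, 1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0131) and regulatory T cell markers (4 of 11 lower, 1, Nrp1 at 2.26 ± 0.27, higher, 1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.00657) shifted down in this difference. Of the markers of other cell types, Cd74 (2.36 ± 0.31), Ctss (1.496 ± 0.26), Hdc (1.47 ± 0.24) and Cd79b (1.33 ± 0.26) moved with the rising lists. In all 710 genes differed upward and 674 downward, 357 and 391 by at least 2-fold, and 1384 together became 1062 without the 2 WT arrays.

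The day 4 WT dose response and the day 2 genotype difference share no array or control. Of 3022 dose and 541 genotype genes, 267 were called in both, 222 in opposite directions. Higher with dose and lower in DKO cells were 141 genes (25.6 if independent), and 81 were the reverse (15.5). Pairs running the same way numbered 13 (15.7) and 32 (25.2). The median log2 genotype change was -0.121 in the 1523 genes higher with dose but -0.0101 in the 1499 lower, not opposed as a set. All genes correlated at -0.234 (Pearson) and -0.0845 (Spearman). The 267 became 168 without WT day 2 replicate 2.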

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

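The tests of admixture and of antigen-presenting cells were chosen after the results were seen; the tests of scaling, single arrays and sample splits were set before their results.

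Activation differed between the genotypes, by a test of the difference itself, in 209 genes. On the log2 scale the response in DKO cells minus that in WT cells was -2.36 for Batf, -3.08 for Il4, -2.96 for Il10, -2.25 for Il13, -3.56 for Il24, -3.13 for Inhba, -2.30 for Bhlhe40, -1.34 for Il12rb1 and -1.08 for Ccr4. It was -1.64 for Ctla4, -1.43 for Hk2, -1.59 for Slc2a3, 2.92 for Ms4a4b, 1.05 for Ctss, 0.75 for Siglech, 1.01 for Ccr7 and 2.05 for Dapl1. As list means it was -0.997 for TH2 genes, -0.31 for effector regulators, 0.37 for naive genes, -0.33 for DNA replication, -0.84 for glycolysis, -0.42 for cholesterol synthesis, -0.39 for amino acids and -0.27 for chaperones. With an estimated correlation only the TH2 call was kept, with adjusted p = 0.0845, 0.468, 0.247, 0.0504, 0.218, 0.0981 and 0.214 for the others in that order.

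The dose response differed between the genotypes in 1384 genes. The difference was -2.03 for Batf3, -2.98 for Il4, -4.52 for Il13, -4.54 for Il24, -4.23 for Il21, -2.44 for Il5, -6.39 for Mt2, -4.68 for Tgm2 and -3.13 for Ahr. It was -2.31 for Fosl2, -3.23 for Il12rb2, -1.70 for Ctla4, -1.40 for Hif1a and -1.33 for Foxp3. Without WT 2.2 ng/ml replicate 3 it was -5.24 for Il24, -5.15 for Il13 and -3.76 for Il4, and without DKO 10 ng/ml replicate 3 -6.98 for Mt2. In the other direction, with all arrays, it was 2.04 for Gzmb, 2.26 for Nrp1, 1.77 for Icos, 3.49 for Tox, 4.01 for Trat1, 1.90 for Hmgcs1, 1.91 for Nsdhl, 3.89 for Scd1, 1.26 for Kif11, 1.57 for Tyms, 1.32 for Slc2a1, 2.36 for Cd74, 1.496 for Ctss, 1.47 for Hdc and 1.33 for Cd79b. As list means it was -0.46 for TH1 markers, -0.45 for regulatory T cell markers, 0.70 for DNA replication, 1.03 for mitosis, 0.92 for glycolysis, 1.35 for cholesterol synthesis and 0.45 for amino acids. DNA replication (adjusted p = 0.0593) and amino acids (0.112) lost the call with an estimated correlation.

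Probe sets without a single gene symbol, left out of the gene tests and used only in the alternative with every probe set, also carried signal: 511 of 13767 were called between the genotypes at 10 ng/ml, 222 higher and 289 lower.

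Of 15 mitosis genes, 10 fell with dose in WT cells and 6 rose in DKO cells, and all 15 cholesterol genes, not called as a list in WT cells, rose in DKO cells. This was weighed against scaling and single arrays. With cyclic loess the mean interaction of the cholesterol list was 1.29 against 1.35 as deposited, which argues against scaling as the whole cause. Leaving out each of the 12 arrays gave at least 1.29, so no single array carried it. A biological hypothesis, tested on the same data in which it was found, is that dose acts on sterol and cell cycle genes differently without Batf and Batf3; other differences between the cultures stay open.

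WT replicate 3 at 2.2 ng/ml stood apart from its group in Irf4 and Il4. If RNA of WT cells at 10 ng/ml had been mixed in, genes higher and lower in that source would imply the same share; they implied 1.28% (117 genes) and 40.2% (25 genes), 38.9 points apart, which argues against it. RNA of WT day 2 cells would need shares of 19.0% (14 genes) and 49.0% (31 genes) to be equal; they lay 30.0 points apart with overlapping quartiles, so admixture of day 2 RNA and an array of another state of the culture cannot be told apart. No biological explanation was tested.

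H2-Ab1 rose 26.1-fold from naive WT cells to WT cells at 10 ng/ml. Antigen-presenting cells in the culture would bring Cd74, H2-Aa and H2-Eb1, among their most abundant transcripts, but the median log2 change of these 3 genes was -0.071, which argues against such cells as the source; the labels name the cells as naive CD4 T cells. Probe sequences were not used here, so signal of another transcript in the H2-Ab1 probe set stays open, and no biological explanation was tested.

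Each comparison of 2 groups has 10 splits of its 6 arrays, and 1 of the 10, the real one, reached the real count in each; 10 splits are too few for a share under 0.05. The real count and the highest of the other splits were 8017 and 0 for WT day 2 against day 0, 7262 and 0 for WT at 10 ng/ml against day 0, 5699 and 0 for DKO day 2 against day 0, 13 and 5 for genotype at day 0, 541 and 0 at day 2, 739 and 1 at 2.2 ng/ml, 2545 and 1 at 10 ng/ml, 3022 and 14 for dose in WT, and 1625 and 1 for dose in DKO. For the difference in activation, 2 of 100 splits that exchanged genotype within a state reached 209, the real one and one with 280. For the difference in dose response, 2 of 100 reached 1384, the real one and one with 1998 that exchanged all genotypes at a single dose and so tested the sum of the genotype effects; the highest of the rest was 1232. Of 100 pairs of splits for the overlap of dose and day 2 genotype calls, the real one gave 267 and the others 0. Those called too few genes to share over 14, so this count decides nothing. Nor do the counts of the 2 differences, as exchanged genotypes carry real effects into them. For list shifts, 1 of 100 random groupings of the 24 arrays reached 108, but another gave 99: co-regulated lists are called readily at the preset correlation, in groupings that mix activated and naive cells.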

How the results depend on the processing

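The alternatives without the 2 WT arrays, without single arrays in the list tests and without Batf and Batf3 in their list were chosen after seeing the data. Of 5101 values of 302 results of 112 named genes under alternatives, 4929 kept their direction and side of the threshold, 154 lost the call, 6 gained it and 12 changed sign; 272 of the 302 results kept both under all. Of 1930 values of 108 list shifts, 1820 kept both, 108 lost the call and 2 changed direction; 62 shifts kept both under all. The 12 changes of sign among genes were in genes not called. Irf4 between genotypes at day 0 was 0.007 under quantile normalization and -0.239 to 0.107 leaving out 1 array; at 2.2 ng/ml it was 0.203 without the 2 WT arrays and -0.367 to 0.203 leaving out 1. Between day 2 and day 0 in DKO cells, Batf was -0.014 under cyclic loess and -0.072 to 0.131 leaving out 1, and Batf3 -0.099 to 0.164. The ribosomal list at WT 10 ng/ml against day 0 changed side, to a mean of 0.03 under cyclic loess and 0.049 under quantile normalization. With every probe set tested, which tests more features, WT day 2 against day 0 gave 12400 calls, WT 10 ng/ml against day 0 11091, DKO day 2 against day 0 8881, the activation difference 124 and genotype at day 0 8. Genotype at day 0 also gave 4 under cyclic loess, 6 with array weights and 2 with its own 6 arrays alone; genotype at 2.2 ng/ml gave 462 with its own arrays alone, where fewer arrays set the spread. List shifts fell from 108 to 66 with an estimated correlation. Beyond the construction of these settings, the cause was not tested.

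Leaving out 1 array, which also lowers the residual degrees of freedom, gave 6767 to 7708 calls for WT day 2 against day 0, 6043 to 6988 for WT 10 ng/ml against day 0, 5061 to 5452 for DKO day 2 against day 0, 98 to 257 for the activation difference, 4 to 14 for genotype at day 0, 298 to 590 for genotype at day 2, 489 to 819 for genotype at 2.2 ng/ml, 1950 to 2368 for genotype at 10 ng/ml, 2288 to 2796 for WT dose, 1058 to 1453 for DKO dose, 1017 to 1578 for the dose difference, 168 to 289 for the overlap of dose and genotype calls, 104 to 112 for the list shifts. The labels do not say what arrays of the same replicate number share. Same-numbered arrays had residual correlations from -0.0956 to 0.264. Every array fitted best with its own number for WT dose only (0.0545, 0.162 and 0.264), a hint from the data and not the design. With the replicate number as a block, every count stayed within 1.5 times, from 13 to 9 for genotype at day 0 and from 739 to 768 at 2.2 ng/ml, with 210 for the activation difference and 3004 for WT dose. Signal over background limits the dim genes: the filter on dim genes left 10555 genes, kept all 255 calls among the 271 gene results it tested and lost 13 of 107 list calls.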

Other observations

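The genes in the next paragraphs were chosen after their values were seen, except that the hypoxia list and its tests were set before their results.

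Ms4a4b stood at 657 ± 64.7 in naive WT cells, 17.2 ± 10.2 at day 2, 286 ± 113 at 2.2 ng/ml and 9.37 ± 1.96 at 10 ng/ml, and in DKO cells at 717 ± 51.4, 129.7 ± 27.8, 678 ± 29.9 and 39.3 ± 13.7.

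Because Egln3, Aldoc and Slc2a1, all known to be induced by low oxygen, rose with dose in DKO cells, a list of 18 further hypoxia-response genes outside the fixed lists was tested. In DKO cells 10 of 18 rose with dose and 0 fell, with a median log2 change of 0.93 (camera p = 0.000368 and adjusted p = 0.00221, with an estimated correlation), among them Bnip3 (3.25 ± 0.26), Vegfa (1.99 ± 0.27) and Fam162a (1.51 ± 0.16). In WT cells 14 of 18 rose, with a median of 0.997 (camera p = 0.00172 and adjusted p = 0.00516, with an estimated correlation). The difference in dose response between genotypes did not pass (camera p = 0.903 and adjusted p = 0.903, with an estimated correlation; 2 genes differed upward and 1 downward), while Hif1a itself was 5.27-fold lower in DKO cells at 10 ng/ml. Adjustment was over the 6 contrasts in which this list was tested. The remaining 3 did not pass with an estimated correlation: DKO against WT at 10 ng/ml (1 higher and 6 lower, adjusted p = 0.148), DKO against WT at 2.2 ng/ml (0 higher and 4 lower, camera p = 0.0424, adjusted p = 0.0848) and WT day 2 against day 0 (9 higher and 1 lower, adjusted p = 0.174). The values are consistent with a hypoxia-like response to the higher dose in both genotypes, as a hypothesis; oxygen and cell density were not measured here.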
